A study of Homo sapiens with 8 samples.

How the data were processed

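The values used were the gene-level FPKM table deposited by the authors, with 1 column per library and values rounded to 2 decimals. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with a SMARTer kit; Flag-OGT was introduced with a lentiviral vector and cells were selected for neomycin resistance. Per the submitters' processing notes, the software comprised Bowtie2, HISAT2 2.1.0, RSEM 1.2.4 and DESeq2 1.18.1 with the hg19 genome. Which of them made the FPKM is not given in the sources used here. The reference at hand was for another genome build, so it served only for gene symbols, transcript length, GC content and gene order, and no coordinates were used. The chromatin immunoprecipitation libraries of the series were not analysed here.

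The table listed 18928 features. Left out were 26 whose symbols had been turned into dates, which held at most 0.100% of the summed FPKM of a library, so 18902 were analysed. Another 55 carried a number in place of a symbol and were tested but never named. Of the features, 18014 had a current symbol, 508 were matched through a synonym and 380 by neither. Of the fixed list of mitochondrially encoded genes, 0 were found. Genes with a mean FPKM of at least 0.5 were tested, 13553 in number. The read depth is unknown.

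The groups, the 4 comparisons, the fixed gene lists, the alternatives and the rule for naming genes were set before the data were examined. The comparisons were Flag-OGT against control in each line, the difference between these effects, and MHCC-97H against MHCC-97L without Flag-OGT. Log2(FPKM + 1) values of all 8 libraries were fitted with 4 group means in limma 3.58.1 (R 4.3.3), with empirical Bayes moderation along a mean-variance trend and 4 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over all tested genes of a comparison and called under 0.05. Called members of a list were also counted with the adjustment made over the list alone. Most genes were called in each comparison, so these counts could differ little and their agreement is no independent check. Lists with at least 5 tested genes, 33 of 36, were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, which compares with no other genes. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

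Named genes were, per comparison, the 6 highest and 6 lowest log2 changes among called genes whose libraries did not overlap, and up to 2 called members at either end of each called list. Members of the O-GlcNAc, epithelial, mesenchymal, secreted hepatocyte and oncofetal lists were taken in any case, as were OGT, OGA, ZNF263 and HCFC1. For the overlap, 6 genes per direction with the largest mean absolute change were taken. HNF4A and the genes of the closing section that lie outside this rule were chosen after their values were seen. Some genes that meet the rule are not reported here.

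Alternatives were a pseudocount of 0.1, no filter, a mean FPKM filter of 2, FPKM rescaled to a common sum, median-of-ratios scaling, quantile normalization, no trend, a fit of 2 groups alone, a replicate block, each library left out and a 2-fold minimum. Removal of a trend with transcript length and GC content, available for 98.2% of tested genes, and the comparison of lines within the Flag-OGT libraries were added after seeing the data.

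The procedure was tested on simulated data of the comparison of Flag-OGT with control in MHCC-97H, with 13553 genes of which 50 were changed at each of 4 sizes. It recovered 80% of genes changed by 0.585 on the log2 scale, 98% of those changed by 1, and 100% of those changed by 2 or 3. Of 194 calls 5 were false, and 0 genes were called where none had been changed. The changed genes were drawn from those with a mean log2(FPKM + 1) over 1, and noise was drawn independently for each gene. In the real data most genes were called and genes may vary together, so these rates do not carry over to it. A list shifted by 0.5 in simulated data was called, with 0 of the other lists.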

Results

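RNA was sequenced from MHCC-97H and MHCC-97L, a pair of human hepatocellular carcinoma cell lines whose names mark a high and a low metastatic potential. Each line was measured without and with stable expression of Flag-OGT, a Flag-tagged copy of O-GlcNAc transferase, the enzyme that attaches single N-acetylglucosamine sugars to serine and threonine residues of nuclear and cytosolic proteins. This gave 4 groups of 2 libraries, MHCC-97H, MHCC-97H Flag-OGT, MHCC-97L and MHCC-97L Flag-OGT. The libraries without Flag-OGT have no genotype label and are called controls; whether they carried an empty vector is not given in the sources used here. The series asks how chromatin-bound OGT and the zinc-finger protein ZNF263 act in these cells, and its chromatin immunoprecipitation part was not analysed here. Levels below are deposited FPKM values, given as mean ± SD over the 2 libraries of a group (n = 2). The number of reads behind them is unknown. Summed FPKM per library ran from 510449 to 613101, and 11044 to 11958 genes per library reached 1 FPKM. The ferritin light chain gene FTL had the highest value in each control library (14035 to 23525 FPKM), and the ribosomal protein gene RPS2 in each Flag-OGT library (15274 to 17757 FPKM).

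OGT, the introduced gene, was higher in the libraries labelled Flag-OGT in both lines. Its level was 32.5 and 34.2 FPKM in the MHCC-97H controls and 59.0 and 58.4 FPKM in the MHCC-97H Flag-OGT libraries, a log2 fold change of 0.80 ± 0.06 (SE; limma, Benjamini-Hochberg adjusted p = 3.0e-07). In MHCC-97L it was 45.7 and 43.9 FPKM in the controls and 51.0 and 54.5 FPKM with Flag-OGT, a log2 fold change of 0.23 ± 0.06 (adjusted p = 3.4e-03). The gain in MHCC-97L was no longer called when the FPKM were rescaled to a common sum (0.11, adjusted p = 0.0982) or by a median-of-ratios factor (0.03, adjusted p = 0.552). The difference between the gains of both lines was 0.57 ± 0.08 on the log2 scale (adjusted p = 1.9e-04). A gene-level value does not separate the introduced coding sequence from the endogenous OGT transcript.

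OGA, which encodes the enzyme that removes the sugar, rose from 13.1 ± 1.19 to 24.8 ± 0.163 FPKM in MHCC-97H and from 10.9 ± 0.247 to 31.2 ± 2.91 FPKM in MHCC-97L. The log2 fold changes were 0.88 ± 0.08 (adjusted p = 2.1e-06) and 1.43 ± 0.08 (adjusted p = 4.9e-08), and the gain in MHCC-97H was smaller by the test of the difference (-0.55 ± 0.11, adjusted p = 1.9e-03). HCFC1, a chromatin cofactor that OGT glycosylates and cleaves, rose from 30.7 ± 3.19 to 59.5 ± 1.99 FPKM in MHCC-97H and from 19.1 ± 0.509 to 37.8 ± 1.07 FPKM in MHCC-97L (adjusted p = 6.0e-07 and 5.9e-07). ZNF263 was at 14.6 ± 1.15 and 14.8 ± 0.686 FPKM in MHCC-97H without and with Flag-OGT (adjusted p = 0.75). In MHCC-97L it was at 14.6 ± 0.573 and 12.8 ± 0.396 FPKM, a log2 fold change of -0.17 ± 0.07 (adjusted p = 0.042), a call lost when any library of MHCC-97L was left out. Of the 15 measured genes of O-GlcNAc cycling and the hexosamine pathway, 5 rose and 9 fell in MHCC-97H, and 8 rose and 5 fell in MHCC-97L; the counts adjusted over the list alone were the same. GFPT2 and UAP1, which act in the synthesis of UDP-N-acetylglucosamine, rose in both lines (GFPT2 from 3.77 ± 0.0283 to 15.6 ± 0.396 FPKM in MHCC-97H), while GFPT1, the main rate-limiting enzyme of that route, fell (from 18.6 ± 1.07 to 3.87 ± 0.53 FPKM in MHCC-97H and by a log2 fold change of -2.02 in MHCC-97L). As a list they did not pass the test in either line (camera adjusted p = 0.263 and 0.892).

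**Figure D1:**
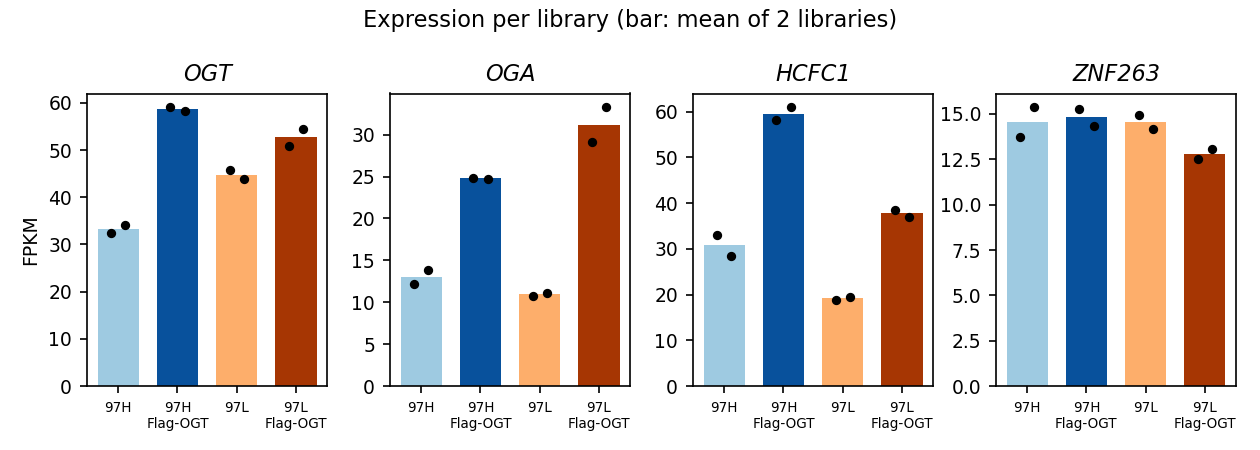
Levels of OGT, OGA, HCFC1 and ZNF263 in FPKM (y axis, from 0) in the 4 groups (x axis); bars are means of 2 libraries and points are single libraries. OGT reaches 58.7 FPKM in MHCC-97H Flag-OGT against 33.3 in its control and 52.8 against 44.8 in MHCC-97L, and ZNF263 lies between 12.8 and 14.8 FPKM in all 4 group means.

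The control libraries of both lines resembled each other, and the Flag-OGT libraries of both lines resembled each other, far more than either resembled the other state of its own line. On log2(FPKM + 1) values across tested genes, replicates correlated with r of 0.997 to 0.999, and libraries of different lines in the same state with r of 0.957 to 0.963. Libraries of the same line in different states correlated with r of only 0.725 to 0.753. Genes are not independent replicates, so these values describe the libraries. The first principal component held 85.4% of the variance and split Flag-OGT from control libraries, and the second, with 8.60%, split the lines. The transcription factor HNF4A, a regulator of hepatocyte identity chosen here after its values were seen, was at 14.6 ± 0.0283 and 13.6 ± 0.346 FPKM in the controls of MHCC-97H and MHCC-97L, and at 0.035 ± 0.00707 and 0.015 ± 0.00707 FPKM with Flag-OGT. Among markers of other cell types fixed in advance, the fibroblast genes COL1A1 and ACTA2 were higher with Flag-OGT (ACTA2 at 15.6 ± 0.601 and 8.81 ± 0.75 FPKM, against control values of 0 in both MHCC-97H libraries and a mean of 0.08 in MHCC-97L), and LUM was lower. The macrophage marker CD68 was at 78.6 ± 1.65 and 63.6 ± 0.205 FPKM in the controls and at 1.13 ± 0.226 and 2.24 ± 0.198 FPKM with Flag-OGT. Other leukocyte markers were low in the controls of MHCC-97H and MHCC-97L, such as PTPRC (0.305 and 0.485 FPKM) and CD14 (0.305 and 0.605 FPKM). ITGAM was lower with Flag-OGT, and LYZ was higher in MHCC-97L (2.79 to 4.685 FPKM). CD68 alone does not show that macrophages were present. Only 3 fibroblast and 3 leukocyte genes were high enough to be tested, too few for a list test.

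**Figure D2:**
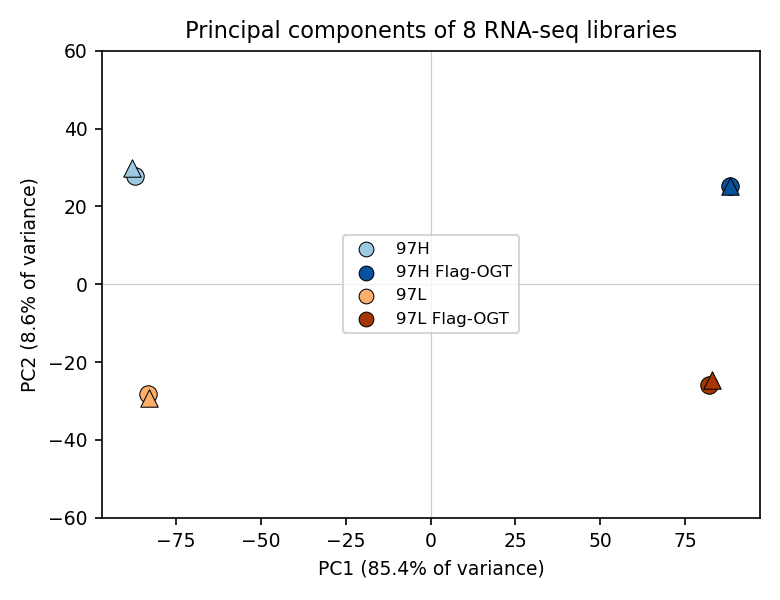
Principal components 1 (85.4% of the variance, x axis) and 2 (8.60%, y axis) of the 8 libraries from log2(FPKM + 1); each point is 1 library, coloured by group, with circles for replicate 1 and triangles for replicate 2. Control libraries lie between -87.9 and -83.0 on component 1 and Flag-OGT libraries between 82.1 and 88.2, and component 2 parts MHCC-97H from MHCC-97L.

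The MHCC-97H Flag-OGT libraries were compared with the controls of MHCC-97H, the line named for high metastatic potential. Whether the Flag-OGT libraries hold RNA of the labelled lines is not settled, as the closing section sets out. Rises and falls in either line are therefore differences between labelled libraries and are not shown to be effects of OGT. Among the 6 steepest gains were those of PHGDH, the first enzyme of serine synthesis, from 1.02 ± 0.0566 to 648 ± 4.45 FPKM (log2 8.33 ± 0.05, adjusted p = 1.4e-13), and of CKB, the brain-type creatine kinase, from 5.93 ± 0.12 to 1447 ± 19.4 FPKM (7.71 ± 0.06, adjusted p = 2.5e-13). DMKN, YBX3, BHMG1 and CITED1 completed the highest 6, with levels of 0.03 to 0.69 FPKM in the controls and 181 to 364 FPKM with Flag-OGT. The 6 deepest losses began with the aldo-keto reductases AKR1B10, from 3276 ± 303 to 1.77 ± 0.566 FPKM (log2 -10.22 ± 0.12, adjusted p = 1.1e-12), and AKR1C1. They went on with the calcium-binding S100A4 and S100A6 (2299 ± 208 to 2.02 ± 0.806 FPKM), C19orf33 (797 ± 4.51 to 0.29 ± 0.0424 FPKM) and AKR1C3.

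Epithelial junction and keratin genes fell in MHCC-97H with Flag-OGT. Of 18 tested members (27 had values), 17 were lower and only OCLN was higher, the same counts when adjusted over the list alone (camera adjusted p = 1.9e-06, adjusted p = 0.0761 with an estimated correlation). KRT8, a keratin of simple epithelia, went from 3846 ± 157 to 10.995 ± 0.148 FPKM and KRT19, a keratin of ductal cells, from 339 ± 33.0 to 0.185 ± 0.0212 FPKM. Integrins, laminins and matrix proteases fell as well, with 25 of 32 lower and 7 higher, also over the list alone (adjusted p = 1.9e-05, adjusted p = 0.0761 with an estimated correlation). ITGB4, the laminin-binding integrin of hemidesmosomes, went from 54.3 ± 5.57 to 0.62 ± 0.0283 FPKM, whereas the basement membrane collagen COL4A1 and the protease ADAMTS1 (0.725 ± 0.0495 to 99.2 ± 0.933 FPKM) rose. Mesenchymal genes went both ways, 10 up and 17 down of 29 (over the list alone also 10 and 17), and the list was not called (adjusted p = 0.0613). VIM, the intermediate filament of mesenchymal cells, rose from 6.65 ± 0.127 to 542 ± 5.52 FPKM. The endothelial marker ESAM fell alongside, from 26.5 ± 0.0354 to 0.555 ± 0.0778 FPKM, with 4 of 5 tested endothelial markers lower and 0 higher, also over the list alone (adjusted p = 0.0165, adjusted p = 0.163 with an estimated correlation).

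Liver genes were among the losses in MHCC-97H. Of 17 tested secreted hepatocyte proteins (31 had values), 15 fell and 0 rose (adjusted p = 1.0e-04, adjusted p = 0.101 with an estimated correlation). They included ITIH2, a hyaluronan-binding inhibitor subunit, from 77.9 ± 1.85 to 0.065 ± 0.0212 FPKM, and apolipoprotein H (APOH) from 26.025 ± 0.997 to 0.08 FPKM in each library. Hepatocyte enzymes, transporters and nuclear factors showed 14 lower and 7 higher of 24 (adjusted p = 0.0199, adjusted p = 0.126 with an estimated correlation), a call lost with median-of-ratios scaling. ALDH1A1, a retinal-oxidizing dehydrogenase, went from 716 ± 43.0 to 0.52 ± 0.0848 FPKM, whereas ASS1 and CPS1 of the urea cycle rose, ASS1 from 1.32 ± 0.0848 to 185 ± 0.587 FPKM. Oncofetal and progenitor markers (7 up, 11 down of 20) were not called as a list (adjusted p = 0.0908). GPC3, a fetal liver proteoglycan, was listed at 0 in the 4 control libraries and reached 29.3 ± 0.544 FPKM, and LIN28B, a repressor of let-7 maturation, reached 5.14 ± 0.0212 FPKM. Fatty acid synthesis genes fell in 14 of 22 and rose in 7 (adjusted p = 0.0388, adjusted p = 0.257 with an estimated correlation, call lost with median-of-ratios or quantile scaling). The desaturase FADS1 went from 41.3 ± 2.77 to 4.06 ± 0.099 FPKM. For these 4 lists too, the counts adjusted over the list alone were the same. HNF4A fell along with these liver genes, to 0.035 FPKM.

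Some stress and signalling lists were lower in MHCC-97H with Flag-OGT, while those of p53 targets, Notch, Wnt, YAP/TEAD, hypoxia and the unfolded protein response were not called. NRF2 targets and metallothioneins had 23 of 27 lower and 3 higher (adjusted p = 1.9e-08, adjusted p = 0.0761 with an estimated correlation); MT1X and MT1F, metal-binding proteins whose reads near-identical family members can share, were among the 3 that rose. Heat shock genes had 18 of 21 lower and 2 higher (adjusted p = 1.8e-04, adjusted p = 0.217 with an estimated correlation). The small heat shock protein gene HSPB1 went from 623 ± 85.1 to 62.6 ± 1.36 FPKM; HSPA1A fell and HSPA1B rose, but both share near-identical sequence and their split is uncertain. Autophagy and lysosome genes fell in 21 of 30 and rose in 6 (adjusted p = 2.1e-03, adjusted p = 0.0832 with an estimated correlation), with the autophagy receptor SQSTM1 going from 796 ± 29.1 to 74.0 ± 2.68 FPKM. Immediate early and MAPK feedback genes were lower in 25 of 32 and higher in 5 (adjusted p = 4.2e-06, adjusted p = 0.0832 with an estimated correlation), with the AP-1 subunit FOSL1 falling from 190 ± 8.95 to 0.71 ± 0.0848 FPKM. NF-kappaB genes were lower in 17 of 22 and higher in 3 (adjusted p = 1.0e-04, adjusted p = 0.077 with an estimated correlation), led by the adhesion receptor ICAM1 (47.6 ± 1.13 to 0.175 ± 0.0636 FPKM). Interferon-stimulated genes fell in 17 of 29 and rose in 8 (adjusted p = 0.0112, adjusted p = 0.101 with an estimated correlation, call lost with a mean FPKM filter of 2). The RNA sensor OAS1 went from 86.2 ± 1.77 to 0.04 ± 0.0566 FPKM. TGF-beta/SMAD targets fell in 13 of 19 and rose in 6 (adjusted p = 0.0213, adjusted p = 0.257 with an estimated correlation, call lost with median-of-ratios scaling), with ID1 going from 414 ± 42.3 to 12.9 ± 0.368 FPKM. In all of these lists the counts adjusted over the list alone were the same, and CD68, the macrophage marker, fell with them (78.6 to 1.13 FPKM).

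A pair of lists rose in MHCC-97H. Cytosolic ribosomal protein genes were higher in 47 of 53 and lower in 5 (adjusted p = 4.5e-06, adjusted p = 0.0832 with an estimated correlation), with RPL29 going from 655 ± 42.8 to 3566 ± 17.1 FPKM and RPL15 from 322 ± 14.2 to 1488 ± 19.6 FPKM. Polycomb and Trithorax chromatin regulators were higher in 28 of 39 and lower in 5 (adjusted p = 8.2e-03, adjusted p = 0.0979 with an estimated correlation). PHC1, a Polycomb repressive complex 1 subunit, rose from 4.76 ± 0.148 to 25.8 ± 0.46 FPKM, and SETD1A, a histone H3 lysine 4 methyltransferase, from 13.3 ± 1.06 to 65.0 ± 1.24 FPKM. Replication-dependent histone genes, which are short and share reads between copies, were lower in 12 of 27 and higher in 3 (adjusted p = 0.0423, adjusted p = 0.163 with an estimated correlation), a call lost under 5 other settings. HIST1H1C, a linker histone, went from 77.1 ± 1.87 to 12.2 ± 1.88 FPKM. The counts adjusted over the list alone were the same for these 3 lists, and the fibroblast marker ACTA2 rose in the same libraries to 15.6 FPKM.

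Over all genes, 11460 of 13553 tested in MHCC-97H were called at an adjusted p under 0.05 (limma), 6537 higher and 4923 lower with Flag-OGT, and 5183 of them changed at least 2-fold (3016 higher, 2167 lower). The excess of higher calls depended on the scaling, with 5775 higher and 5671 lower (2630 and 2549 at 2-fold) with median-of-ratios and 5925 and 5603 with quantile normalization. The median gene moved by 0.15 on the log2 scale, and by 0.01 with median-of-ratios scaling. Of 33 lists tested, 16 were called by camera, 2 up and 14 down, and 0 with an estimated correlation; by fry, which tests whether the genes of a list move on balance one way, 31 passed. Median, mean and camera direction differed in sign for 3 lists, none of them called. The p-values measure only the spread between these libraries, which may be technical, since the RNA libraries are not stated to come from separate cultures. Fold changes on the log2(FPKM + 1) scale understate the change of low genes.

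**Figure D3:**
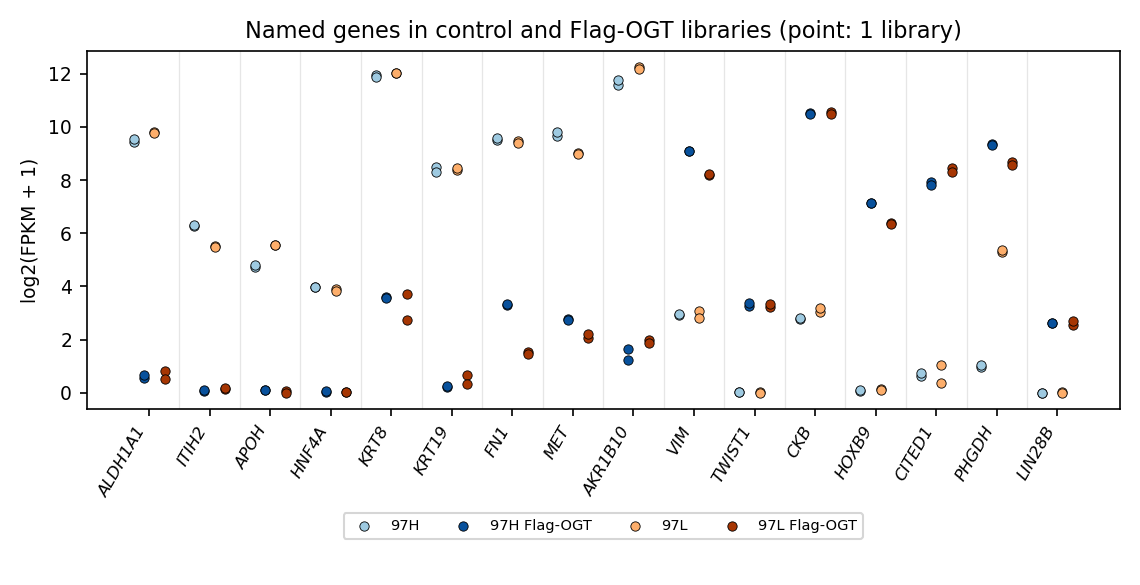
Levels of 16 genes as log2(FPKM + 1) (y axis) in the 8 libraries; each point is 1 library, coloured by group. The 16 genes are HNF4A and genes named because they were called. That control and Flag-OGT libraries do not overlap for any of them follows from this choice and is no test. AKR1B10 lies at means of 3276 and 4741 FPKM in the controls and at 1.77 and 2.83 FPKM with Flag-OGT. CKB lies at 5.93 and 7.67 against 1447 and 1472 FPKM.

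In MHCC-97L, the line named for low metastatic potential, the Flag-OGT libraries were compared with the controls in the same way. CITED1, a transcriptional co-regulator, rose from 0.665 ± 0.544 to 333 ± 24.2 FPKM (log2 7.69 ± 0.17, adjusted p = 5.2e-11) and CKB from 7.67 ± 0.665 to 1472 ± 54.1 FPKM (7.41 ± 0.06, adjusted p = 2.5e-13). DMKN, YBX3, PYCR1 (an enzyme of proline synthesis) and the homeobox gene HOXB9 (0.10 ± 0.0283 to 81.8 ± 1.36 FPKM) completed the highest 6. The deepest losses were in AKR1B10, from 4741 ± 180 to 2.83 ± 0.177 FPKM (log2 -10.27 ± 0.12, adjusted p = 1.2e-12), S100A6, S100A4, AKR1C1, the glutathione peroxidase GPX2 and ALDH1A1 (891 ± 12.5 to 0.61 ± 0.24 FPKM).

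Epithelial and adhesion genes fell in MHCC-97L. Of 18 epithelial genes 15 were lower and 2 higher (adjusted p = 1.4e-05), with KRT8 going from 4134 ± 8.49 to 8.82 ± 4.53 FPKM and the desmosomal DSP rising from 15.2 ± 0.0848 to 22.2 ± 0.17 FPKM. Of 32 integrin, laminin and protease genes 23 were lower and 5 higher (adjusted p = 3.4e-06); MMP7, a secreted protease, went from 198 ± 1.30 to 0.075 ± 0.0354 FPKM. Both calls held with an estimated correlation (adjusted p = 0.0395 each). Mesenchymal genes were lower in 18 of 29 and higher in 10 (adjusted p = 0.0140, adjusted p = 0.188 with an estimated correlation, call lost with median-of-ratios scaling). Fibronectin (FN1) fell from 692 ± 16.7 to 1.84 ± 0.113 FPKM, whereas VIM rose from 6.66 ± 1.00 to 295 ± 8.56 FPKM and the transcription factor TWIST1 from 0.015 ± 0.0212 to 8.76 ± 0.509 FPKM. Drug efflux and growth factor receptor genes were lower in 15 of 24 and higher in 8 (adjusted p = 0.0398, adjusted p = 0.224 with an estimated correlation, call lost under 4 other settings), with the hepatocyte growth factor receptor MET going from 513 ± 12.4 to 3.40 ± 0.332 FPKM and FGFR1 from 0.76 ± 0.0707 to 22.4 ± 0.205 FPKM. The counts adjusted over the list alone were the same, and the endothelial list fell beside them (5 of 5 lower, also over the list alone, adjusted p = 5.3e-03, adjusted p = 0.133 with an estimated correlation).

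All 17 tested secreted hepatocyte proteins, of 31 with values, fell in MHCC-97L (adjusted p = 2.5e-08, adjusted p = 0.0452 with an estimated correlation). APOH went from 46.2 ± 0.615 to 0.025 ± 0.0354 FPKM and AMBP, the precursor of alpha-1-microglobulin, from 43.4 ± 1.15 to 0.06 ± 0.0283 FPKM. Hepatocyte enzymes and factors fell in 18 of 24 and rose in 5 (adjusted p = 2.3e-04, adjusted p = 0.0459 with an estimated correlation). UGT1A1, a bilirubin glucuronosyltransferase whose locus shares exons with related genes, was at 30.9 ± 1.83 FPKM in the controls and listed at 0 in both Flag-OGT libraries. Oncofetal markers fell in 13 of 20 and rose in 6 (adjusted p = 9.2e-03, adjusted p = 0.198 with an estimated correlation); the secreted phosphoprotein SPP1 went from 344 ± 0.919 to 0.13 ± 0.0283 FPKM and LIN28B reached 5.17 ± 0.537 FPKM. Fatty acid synthesis genes fell in 15 of 22 and rose in 4 (adjusted p = 2.8e-03, adjusted p = 0.157 with an estimated correlation), with the lipid droplet protein CIDEC going from 114 ± 3.55 to 4.80 ± 0.573 FPKM. Counts adjusted over the list alone were the same for these lists, and HNF4A fell in the same libraries, to 0.015 FPKM.

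Some signalling and stress lists were lower in MHCC-97L as well, while those of heat shock genes, p53 targets, Notch, Wnt, YAP/TEAD, hypoxia and the unfolded protein response were not called. Immediate early and MAPK feedback genes were lower in 31 of 32, with EPHA4 the only one higher (adjusted p = 8.6e-11), and the ETS factor ETV4 went from 57.4 ± 2.02 to 0.35 ± 0.113 FPKM. NF-kappaB genes were lower in 19 of 22 and higher in 2 (adjusted p = 3.5e-06), with the siderophore-binding LCN2 falling from 63.8 ± 3.03 to 0.035 ± 0.0495 FPKM, and NRF2 targets in 23 of 27 with 3 higher (adjusted p = 4.1e-09). These 3 calls held with an estimated correlation (adjusted p = 0.0395 each). Interferon-stimulated genes were lower in 20 of 29 and higher in 7 (adjusted p = 2.8e-03, adjusted p = 0.0662 with an estimated correlation), among them LGALS3BP (675 ± 14.7 to 8.12 ± 1.202 FPKM). Autophagy genes were lower in 16 of 30 and higher in 5 (15 and 5 adjusted over the list alone, adjusted p = 2.8e-03, adjusted p = 0.0662 with an estimated correlation). TGF-beta/SMAD targets were lower in 13 of 19 and higher in 5 (adjusted p = 9.0e-03, adjusted p = 0.198 with an estimated correlation). Apart from autophagy, counts adjusted over the list alone were the same. CD68 fell in these libraries from 63.6 to 2.24 FPKM.

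Of the growth-related lists, 3 rose in MHCC-97L with the Polycomb list, while G2/M and mitosis genes were not called (adjusted p = 0.519). Cytosolic ribosomal protein genes were higher in 50 of 53 and lower in 2 (adjusted p = 1.1e-08, adjusted p = 0.0395 with an estimated correlation), with RPS6 going from 589 ± 1.68 to 3371 ± 227 FPKM. DNA replication and G1/S genes were higher in 24 of 32 and lower in 2 (adjusted p = 5.5e-03, adjusted p = 0.203 with an estimated correlation). CDC45, a component of the replicative helicase, rose from 22.4 ± 0.933 to 108 ± 2.00 FPKM, and cyclin D1 (CCND1) fell from 50.4 ± 0.424 to 16.6 ± 0.41 FPKM. MYC-responsive ribosome biogenesis genes were higher in 22 of 30 and lower in 5 (adjusted p = 0.0344, adjusted p = 0.142 with an estimated correlation, call lost when rescaled to a common sum or by median-of-ratios), including ornithine decarboxylase ODC1 (31.6 ± 0.127 to 93.1 ± 3.58 FPKM). Polycomb and Trithorax regulators were higher in 29 of 39 and lower in 6 (adjusted p = 0.0326, adjusted p = 0.133 with an estimated correlation, call lost with median-of-ratios scaling). RBBP7, a histone-binding subunit, rose from 31.2 ± 0.778 to 157 ± 15.3 FPKM. The counts adjusted over the list alone were the same for these 4 lists, beside a rise of ACTA2 to 8.81 FPKM.

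In total 11494 of 13553 genes were called in MHCC-97L (limma), 6792 higher and 4702 lower with Flag-OGT, of which 4704 changed at least 2-fold (2523 higher, 2181 lower). With median-of-ratios scaling 5832 were higher and 5582 lower, and the 2-fold split turned, to 1971 higher and 2505 lower (2525 and 2565 when rescaled to a common sum). The median gene moved by 0.19 on the log2 scale, and by 0.03 with median-of-ratios scaling. Camera called 19 of 33 lists, 4 up and 15 down, and 8 with an estimated correlation, those named above; fry passed 33. Median, mean and camera direction differed in sign for 2 lists, neither called.

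**Figure D4:**
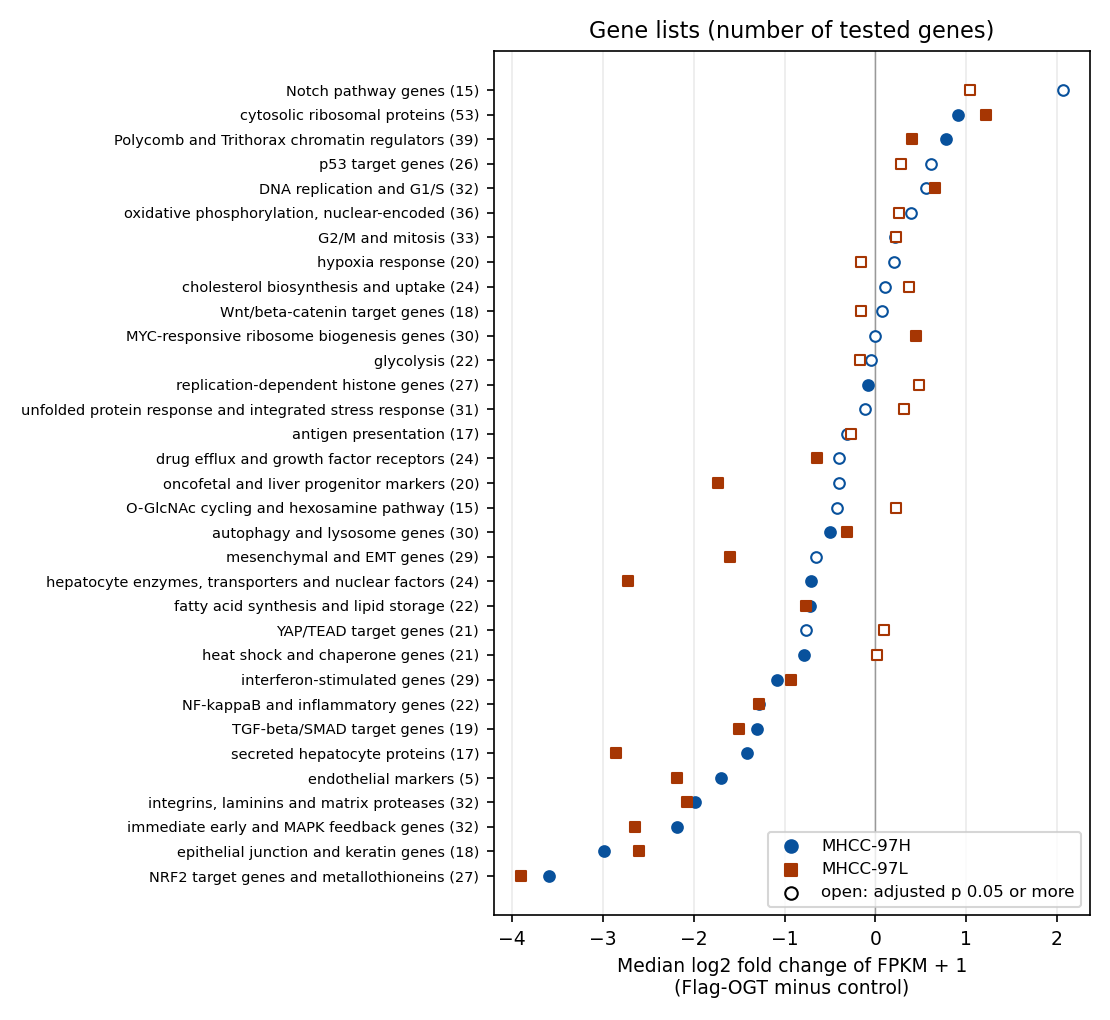
Median log2 fold change of FPKM + 1, Flag-OGT minus control (x axis), of each of 33 fixed gene lists (y axis, with the number of tested genes); circles are MHCC-97H and squares MHCC-97L, filled where the camera adjusted p with the preset correlation is under 0.05. NRF2 targets have the lowest medians, -3.60 and -3.90, and ribosomal protein genes lie at 0.91 and 1.22.

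Genes called in both lines mostly moved the same way. Of them, 5417 rose in both lines and 3716 fell in both, against 3276 and 1708 that independent lists of these sizes would share, and 894 went in opposite directions, against 4735; the Flag-OGT contrasts of both lines share no library. The balance of shared rises and falls depended on the scaling, with 4583 and 4467 with median-of-ratios and 5047 and 4040 when rescaled to a common sum. Among changes of at least 2-fold, 1929 genes rose and 1631 fell in both lines and 19 were opposite. The fold changes correlated across genes with r = 0.884. The genes with the largest mean gains were DMKN, YBX3, CKB, CITED1, HOXB9 (0.055 ± 0.0212 to 141 ± 0.247 FPKM in MHCC-97H) and PYCR1 (0.31 ± 0.311 to 153 ± 0.856 FPKM). Those with the largest mean losses were AKR1B10, AKR1C1, S100A6, S100A4, GPX2 (819 ± 15.1 to 0.555 ± 0.0636 FPKM in MHCC-97H) and AKR1C3.

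The change between control and Flag-OGT libraries was then compared between the lines, as the change in MHCC-97H minus the change in MHCC-97L. BHMG1 had the most positive difference (7.17 ± 0.09, adjusted p = 1.5e-10), being at 181 ± 0.757 FPKM in MHCC-97H Flag-OGT and at 0.355 FPKM or less in the means of the other groups. SH3BGR (5.42), like BHMG1, was high in MHCC-97H Flag-OGT alone, at 76.2 ± 0.368 FPKM. TSPAN8, a tetraspanin, and CST1, a cystatin, were high in the MHCC-97L controls alone (75.2 ± 8.15 and 45.5 ± 0.728 FPKM) and gave differences of 5.27 and 5.04. HTRA3 (5.06) rose in MHCC-97H and fell in MHCC-97L, from 12.7 ± 0.0212 to below 1 FPKM. PHGDH (5.05) rose in both lines, from a control level of 1.02 FPKM in MHCC-97H and 39.5 ± 1.23 FPKM in MHCC-97L. On the negative side, ARRDC5 (-4.98; 35.0 ± 0.0495 FPKM) and the histone gene HIST1H4J (-4.48; 21.3 ± 0.226 FPKM) were high in MHCC-97L Flag-OGT alone. PTHLH (-3.88), CSAG1 (-3.79) and MAGEA12 (-3.37) were high in the MHCC-97H controls, and the cochaperone DNAJC12 (-3.87) rose in MHCC-97L from 1.30 ± 0.0283 to 18.7 ± 1.08 FPKM.

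Lists of liver genes were among those whose change differed. The difference takes in the control libraries, which already differed for these genes. There, 14 of 17 secreted hepatocyte proteins were lower in MHCC-97H and 2 higher, and 17 of 24 hepatocyte enzymes and factors were lower and 3 higher. For a gene near 0 with Flag-OGT in both lines, such as SERPINA1, the difference largely restates the control levels. How much of the list results this accounts for was not tested. Secreted hepatocyte proteins had 13 of 17 more positive in MHCC-97H and 2 more negative (adjusted p = 7.5e-04, adjusted p = 0.200 with an estimated correlation), with SERPINA1, the alpha-1-antitrypsin gene, at 0.49 ± 0.0424 FPKM in MHCC-97H controls, 27.8 ± 0.551 in MHCC-97L controls and 0.155 and 0.415 with Flag-OGT. Hepatocyte enzymes had 13 and 2 of 24 (adjusted p = 0.0115, adjusted p = 0.200 with an estimated correlation), among them ASS1 (4.64 ± 0.08). Notch pathway genes had 10 and 1 of 15 (10 and 2 adjusted over the list alone, adjusted p = 5.5e-03, adjusted p = 0.200 with an estimated correlation); the receptor NOTCH3 rose to 22.1 ± 0.0424 FPKM in MHCC-97H and 5.80 ± 0.297 in MHCC-97L. Targets of p53 had 15 and 3 of 26 (16 and 3 adjusted over the list alone, adjusted p = 0.0205, adjusted p = 0.200 with an estimated correlation), led by PHLDA3 (3.20 ± 0.11), a repressor of AKT. Hypoxia genes had 12 and 2 of 20 (13 and 2 adjusted over the list alone, adjusted p = 0.0179, adjusted p = 0.355 with an estimated correlation). DDIT4, an inhibitor of mTORC1, rose from 5.22 ± 0.396 to 85.7 ± 1.86 FPKM in MHCC-97H and was at 14.6 ± 0.544 and 16.4 ± 0.113 FPKM in MHCC-97L. The p53 and hypoxia calls were lost with a mean FPKM filter of 2. The libraries compared here stand apart by state (r of 0.725 to 0.753 within a line), for these lists as for those that follow.

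Replication-dependent histone genes were more negative in MHCC-97H in 18 of 27 and more positive in 1 (adjusted p = 5.4e-05, adjusted p = 0.126 with an estimated correlation). HIST1H2BK went from 139 ± 10.1 to 62.4 ± 0.191 FPKM in MHCC-97H and from 60.6 ± 1.14 to 209 ± 3.46 FPKM in MHCC-97L. MYC-responsive ribosome biogenesis genes had 20 more negative and 3 more positive of 30 (23 and 3 adjusted over the list alone, adjusted p = 1.9e-04, adjusted p = 0.126 with an estimated correlation). MYC itself went the other way, rising from 35.8 ± 0.962 to 102 ± 0.778 FPKM in MHCC-97H and falling from 29.1 ± 0.721 to 20.8 ± 1.02 FPKM in MHCC-97L. Heat shock genes had 14 and 3 of 21 (adjusted p = 3.8e-03, adjusted p = 0.363 with an estimated correlation); the chaperone HSP90AA1 went from 204 ± 14.1 to 105 ± 1.14 FPKM in MHCC-97H and from 248 ± 10.5 to 437 ± 26.1 FPKM in MHCC-97L. Ribosomal protein genes had 26 and 7 of 53 (adjusted p = 5.5e-03, adjusted p = 0.240 with an estimated correlation), and the direction of this list turned with quantile normalization (adjusted p = 0.837). O-GlcNAc and hexosamine genes had 10 and 1 of 15 (adjusted p = 0.0457, adjusted p = 0.241 with an estimated correlation, call lost when any of 4 single libraries was left out), OGT being the 1 more positive. RENBP, a renin-binding epimerase, fell from 15.5 ± 1.181 to 1.23 ± 0.29 FPKM in MHCC-97H and was at 5.80 ± 0.0354 and 4.83 ± 0.438 FPKM in MHCC-97L. Where not given, counts adjusted over the list alone were the same.

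By the test of the difference, the change between control and Flag-OGT libraries differed between the lines for 8576 of 13553 genes (limma), 4597 more positive and 3979 more negative in MHCC-97H. At least 2-fold differences were found for 1679, 1231 more positive and 448 more negative. With quantile normalization 9028 were called, 4083 more positive and 4945 more negative. When rescaled to a common sum, 4958 were more positive and 3413 more negative. Camera called 10 lists, 5 in each direction, and 0 with an estimated correlation, while fry passed 28. With a mean FPKM filter of 2 it called 3 positive and 4 negative lists, and with quantile normalization 6 positive and 3 negative. Signs of median, mean and camera direction differed for 4 lists, none called.

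The control libraries compare the lines themselves. PTHLH, the gene of parathyroid hormone-related protein, was at 21.7 ± 0.099 FPKM in MHCC-97H and 0.445 ± 0.148 in MHCC-97L (log2 3.98 ± 0.09, adjusted p = 1.9e-09). The cancer-testis genes CSAG1 (48.2 ± 1.44 against 2.60 ± 0.686 FPKM) and MAGEA12, the matrix proteoglycan VCAN (11.2 ± 0.396 against 0.18 ± 0.0283 FPKM), the amino acid carrier SLC38A5 and DPYSL3 were also higher in MHCC-97H. Higher in MHCC-97L were CST1, TSPAN8, the surface glycoprotein CD24 (84.7 ± 0.933 against 1.52 ± 0.205 FPKM; log2 -5.09 ± 0.09, adjusted p = 3.9e-10), the alcohol dehydrogenase ADH1C (66.6 ± 1.40 against 1.58 ± 0.226 FPKM), PHGDH and the cytochrome P450 gene CYP2B6. OGT itself was lower in MHCC-97H (33.3 ± 1.15 against 44.8 ± 1.29 FPKM; log2 -0.42 ± 0.06, adjusted p = 1.3e-04).

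Secreted hepatocyte proteins were lower in MHCC-97H in 14 of 17 and higher in 2 (adjusted p = 1.6e-04, adjusted p = 0.190 with an estimated correlation), apolipoprotein E (APOE) being at 1.01 ± 0.41 against 33.5 ± 1.21 FPKM. Hepatocyte enzymes and factors were lower in 17 of 24 and higher in 3 (adjusted p = 0.0143, adjusted p = 0.190 with an estimated correlation, call lost with a mean FPKM filter of 2), and the bile acid receptor NR1H4 was at 0.28 ± 0.0283 against 9.07 ± 0.219 FPKM. Nuclear-encoded oxidative phosphorylation genes were lower in 26 of 36 and higher in 7 (adjusted p = 9.8e-03, adjusted p = 0.190 with an estimated correlation, call lost after removal of a length and GC trend). COX5B was at 191 ± 8.81 against 442 ± 16.1 FPKM. Interferon-stimulated genes were lower in 15 of 29 and higher in 2 (14 and 2 adjusted over the list alone, adjusted p = 0.0477, adjusted p = 0.206 with an estimated correlation, call lost under 3 other settings), including the antiviral IFITM2 (7.26 ± 1.46 against 32.8 ± 0.184 FPKM). Replication and G1/S genes were higher in MHCC-97H in 21 of 32 and lower in 3 (adjusted p = 1.4e-04, adjusted p = 0.206 with an estimated correlation), among them MCM10 (14.0 ± 0.764 against 5.47 ± 0.00707 FPKM). YAP/TEAD targets were higher in 14 of 21 and lower in 5 (adjusted p = 9.2e-03, adjusted p = 0.190 with an estimated correlation), with ANKRD1 at 13.1 ± 0.403 against 0.965 ± 0.318 FPKM and IGFBP3 opposite at 0.955 ± 0.0354 against 24.9 ± 0.551 FPKM. MYC-responsive ribosome biogenesis genes were higher in 16 of 30 and lower in 5 (adjusted p = 0.0129, adjusted p = 0.190 with an estimated correlation), and heat shock genes in 11 of 21 with 4 lower (adjusted p = 0.0393, adjusted p = 0.470 with an estimated correlation, call lost with a mean FPKM filter of 2). HSPA8, the constitutive HSP70, was at 951 ± 92.03 against 312 ± 11.1 FPKM. Unless given, counts adjusted over the list alone were the same.

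Among epithelial genes, which were not called as a list (adjusted p = 0.222), KRT7 was lower in MHCC-97H (17.9 ± 2.31 against 74.5 ± 4.30 FPKM) and the plakophilin PKP2 higher (10.8 ± 0.339 against 2.12 ± 0.00707 FPKM). In all, 8859 of 13553 genes differed between the control groups (limma), 3589 higher and 5270 lower in MHCC-97H, and 1036 at least 2-fold (297 higher, 739 lower). The split of all calls depended on the scaling. It turned to 4646 higher and 4297 lower when rescaled to a common sum and to 4547 and 3963 with quantile normalization, and was nearly even with median-of-ratios (4404 and 4526), while the 2-fold split kept its direction under each. Camera called 8 lists and 0 with an estimated correlation, and fry passed 27; without MHCC-97H replicate 2, camera called 12. For 5 lists, none called, the signs of median, mean and camera direction differed. A comparison of the lines within the Flag-OGT libraries, added after seeing the data, called 9445 genes, 4551 higher and 4894 lower in MHCC-97H Flag-OGT (5900 and 3541 when rescaled to a common sum). BHMG1 was at 181 FPKM in MHCC-97H Flag-OGT against 0.355 in MHCC-97L Flag-OGT, GPC3 at 29.3 against 4.21, and TSPAN8, at 0.97 and 75.2 FPKM in the controls, was listed at 0 in all 4 Flag-OGT libraries.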

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

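The gene dosage slope below was chosen only after the results were seen; the comparison of line differences was set before its value was computed. The change between control and Flag-OGT libraries differed between the lines, by the test of the difference, for 8576 genes, and 894 genes were called in opposite directions in both lines. The largest log2 differences of the effect, MHCC-97H minus MHCC-97L, were in BHMG1 (7.17), SH3BGR (5.42), TSPAN8 (5.27), HTRA3 (5.06), PHGDH (5.05) and CST1 (5.04). At the other end were ARRDC5 (-4.98), HIST1H4J (-4.48), PTHLH (-3.88), DNAJC12 (-3.87), CSAG1 (-3.79) and MAGEA12 (-3.37). The same test separated the lines for OGT (0.57) and OGA (-0.55).

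By the list test of the difference, the median log2 difference was positive for secreted hepatocyte proteins (1.44), Notch pathway genes (0.72), hepatocyte enzymes, transporters and nuclear factors (0.61), hypoxia genes (0.54) and p53 targets (0.39). It was negative for replication-dependent histone genes (-0.98), heat shock genes (-0.69), MYC-responsive ribosome biogenesis genes (-0.58), O-GlcNAc and hexosamine genes (-0.38) and cytosolic ribosomal proteins (-0.18). All 10 of these calls were lost with an estimated correlation. Both lists of liver genes were also called lower in MHCC-97H between the control lines, and those control levels enter the difference.

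Some of these genes, such as TSPAN8, set the control lines apart and were low in both Flag-OGT groups. The MHCC-97H minus MHCC-97L difference was compared without and with Flag-OGT across 10343 genes at 1 FPKM or more in both states. Genes near 0 in either state were thus left out. The correlation was r = 0.294 (95% bootstrap 0.272 to 0.321). It was 0.286 on the TPM scale, 0.293 with median-of-ratios, 0.283 with quantile normalization and 0.261 with a length and GC trend removed. All lie under the 0.3 set in advance for lines that keep their differences, so whether the Flag-OGT libraries may keep them stays open. Of 5370 genes called in both states, 3852 had the same sign (71.7%). Of all 65 genes at least 4-fold apart in the controls, 24 were called with the same sign. The 71.7% counts only genes called in both states, so it cannot be set against 24 of 65. On the wider base the count was 3852 of 10343 genes. The slope of window means over neighbouring genes, with Flag-OGT on without, was 0.156 (0.0637 to 0.252), with r = 0.440 over 47 windows. The SD of these window means was 0.213 between the control lines, over the highest value from shuffled gene orders (0.0682). Between the Flag-OGT groups it was 0.0758, over the median shuffled value (0.0568) but under the highest (0.0788), which does not exclude weak regional differences. The regional differences of the control lines were thus not kept in full, and little of them was seen with Flag-OGT. How much of the regional difference between the control lines is gene dosage was not measured. Whether the Flag-OGT libraries carry the dosage of the labelled lines therefore stays open.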

How the results depend on the processing

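Removal of a length and GC trend was chosen after seeing the data, and the cause of the shifts below was not tested. A 2-fold minimum left 5183 genes for Flag-OGT in MHCC-97H, 4704 in MHCC-97L, 1679 for the difference between lines, 1036 between the control lines and 3560 in the overlap. With an estimated correlation, camera called 0, 8, 0 and 0 lists in these 4 comparisons, and fry called 31, 33, 28 and 27. The gain of OGT in MHCC-97L shrank to 0.11 when rescaled to a common sum (TPM scale) and to 0.034 with median-of-ratios scaling, and neither passed. Leaving out each library gave 10821 to 11489 genes for MHCC-97H, 10934 to 11632 for MHCC-97L, 7476 to 8591 for the difference, 7548 to 8921 between the controls and 8788 to 9121 in the overlap; OGT ran from 0.76 to 0.83 in MHCC-97H and from 0.18 to 0.28 in MHCC-97L. Replicate numbers did not pair the libraries (r of replicate differences between groups from -0.206 to 0.309), and with the replicate block in the fit only ZNF263 in MHCC-97L lost its call among named genes (adjusted p = 0.0548).

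The direction of some results turned. ZNF263 in MHCC-97H went to -0.0277 on the TPM scale, -0.148 with median-of-ratios, -0.0295 with quantile normalization and -0.256 with the length and GC trend removed (adjusted p = 5.3e-03), and ran from -0.0496 to 0.101 over left-out libraries, with -0.0186 without replicate 1 of MHCC-97H Flag-OGT. Between the control lines ZNF263 went to 0.127 (TPM scale), 0.0875 (median-of-ratios), 0.0308 (quantile) and 0.0651 (length and GC), and from -0.0772 to 0.0733 over left-out libraries, with 0.0356 without replicate 1 of MHCC-97L. Its difference of the Flag-OGT effect went to -0.0751 with the length and GC trend removed. The difference for HCFC1 went to 0.0459 (TPM scale), 0.00147 (median-of-ratios) and 0.0222 (quantile), and from -0.115 to 0.0909 over left-out libraries. JAG1 turned to 0.277 at a pseudocount of 0.1. The difference for the cytosolic ribosomal proteins list turned with quantile normalization (adjusted p = 0.837). The oncofetal list between the control lines turned without a trend (adjusted p = 0.995), with the replicate block (0.972) and with 2 groups alone (0.992), and its adjusted p ran from 0.939 to 0.999 over left-out libraries, the lowest without MHCC-97H replicate 2.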

Other observations

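The HEK293 lineage list, its test and the window test were set after the libraries were seen to stand apart, and the mixture test and the length and GC test only after their results were seen; the genes named here were chosen after their values were seen. Beside the genes above, 41 genes were at 0.1 FPKM or less in all 4 control libraries and at 10 or more in all 4 Flag-OGT libraries, and 46 the reverse. The first set included the homeobox genes HOXD13 (0.03 ± 0.0141 to 45.7 ± 1.46 FPKM in MHCC-97H, 0.01 ± 0.0141 to 22.3 ± 0.0354 in MHCC-97L) and EN2 (26.2 ± 1.29 and 30.4 ± 0.438 FPKM with Flag-OGT). The insulin receptor substrate IRS4 went from 0.06 ± 0.0283 to 141 ± 1.66 FPKM in MHCC-97H and from 0.04 ± 0.0424 to 62.2 ± 5.17 in MHCC-97L. MTHFD2, a mitochondrial folate enzyme, reached 91.7 ± 1.81 and 53.01 ± 5.25 FPKM with Flag-OGT. The reverse set included VIL1, a brush border protein (23.5 ± 0.58 and 14.5 ± 0.396 FPKM in the controls, 0.04 FPKM with Flag-OGT in both lines), and the DNA repair gene MGMT (22.0 ± 1.41 and 34.1 ± 1.34 FPKM in the controls).

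The libraries of both lines changed together, to an extent that may reflect other cells under the Flag-OGT label. A list of 14 genes of the HEK293 lineage, written before their values were looked at, had 10 called higher in both lines, a share of 0.714, under the 0.8 set in advance. Only 12 of the 14 were high enough to be tested, and among all tested genes 5417 of 13553 were called higher in both lines. The 12 tested HEK293 lineage genes had a median log2 change of 2.29, above the highest of 10000 matched lists (1.33). TMEM173, silent in HEK293T cells, was at 0.495 ± 0.0495 FPKM in MHCC-97L Flag-OGT but at 2.94 ± 0.361 in MHCC-97H Flag-OGT, so RNA of a HEK293T-type line and Flag-OGT alone cannot be told apart here. The changes clustered along chromosomes at least 3.36 times as much as in shuffled gene orders, over the 1.5 set in favour of Flag-OGT alone but under the bound set against it, 1.5 times the 4.19 between the control lines, so it stays open (1.33 between the Flag-OGT groups of both lines), and with a length and GC trend removed the count of changes of 2-fold or more was at least 0.965 times that before, which argues against that bias as the whole cause.

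Levels near 0 of many hepatocyte genes in the Flag-OGT libraries could arise if labelled cells were mixed with others. The lowest share kept among 15 hepatocyte genes at 10 FPKM or more in the MHCC-97H controls was 0.0726%, and 6 kept under 1%, which leaves no room for a mixture with 10% of unchanged labelled cells. The other 9 kept more, such as CEBPA (26.9%) and ALDH2 (48.1%), while PCK2 and GLUL rose in both lines and ASS1 in MHCC-97L reached 331.5% of its control. Short tandem repeat typing of the cells behind each library would settle their identity, and variant calls from the reads could be compared between control and Flag-OGT libraries of a line (window ratio 3.36, slope 0.156). Whether control and Flag-OGT libraries were processed together is not given in the sources used here.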
